A study of Homo sapiens with 8 samples.

How the data were processed

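RNA was sequenced from 8 samples of primary human airway epithelial cells grown and differentiated at an air-liquid interface. The series' labels put 3 samples in a group exposed to exosomes from activated neutrophils, 3 in a group exposed to exosomes from quiescent neutrophils and 2 in a group given PBS alone. Groups and replicate numbers were taken from the sample titles. The descriptions of the 2 PBS samples carry other numbers than their titles (2 and 3 in place of 1 and 2), and the title numbers are used as names here.

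The values are whole-number counts of reads per gene, deposited by the authors as 1 table for all 8 samples. Per the submitters' processing notes, bcl2fastq 2.18.0.12, STAR 2.5.3, HTSeq 0.9.1 and DESeq2 1.18.1 were used with the GRCh38 build. The role of each tool, the library kit, the strand setting, the read length and the annotation release are not given in the sources used here. The deposited table ends with the 5 summary rows that HTSeq writes, of which 2 are 0 in all 8 libraries. These rows name no gene and were left out of library sizes and tests. Records that were not uniquely aligned made up 44.1% to 80.4% of all records per library, counting gene rows and summary rows together. HTSeq counts alignment records in this row, so 1 read may enter it more than once. Reads from near-identical gene copies are lost to it or divided between copies, and without a stated strand setting, overlapping and antisense genes cannot be told from their neighbours.

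The table holds 58096 versioned Ensembl gene identifiers. A symbol other than the identifier itself was found for 41445 of them (71.3%). Of all identifiers, 53747 (92.5%) occur with the same version in GENCODE release 29, from which positions on GRCh38 and older symbols were taken. Of the genes tested, 92.2% have a symbol.

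Gene counts summed to between 18592010 and 26366985 per library. Differential expression was tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by group with its minimum count of 10, TMM normalisation (factors 0.972 to 1.02), robust dispersion and quasi-likelihood F tests, with all 8 samples in 1 fit and no covariate. This left 17249 genes. The contrasts were activated against PBS, quiescent against PBS, activated against quiescent, the mean of both exosome groups against PBS, and any difference among the 3 groups. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Levels are CPM as computed by edgeR on TMM-scaled library sizes, given as mean ± SD. Fold changes are log2 values with a standard error (SE), computed as the absolute log2 difference divided by the square root of its F statistic. Nothing in the labels says whether the samples of a group came from separate donors, cultures or days, so p-values measure the spread between these samples, which may be technical.

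A set of 32 gene lists was fixed before the data were examined, together with the tests, their alternatives and the rule for named genes. The lists cover airway cell types, inflammation and innate defence, matrix and junctions, stress, metabolism, proliferation, signs of RNA quality, and cell types other than airway epithelium. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1, on voom values with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Camera with the preset correlation takes members of a list to be nearly independent, and a state that moves all members of a list in 1 culture then counts as many observations.

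The rule for named genes took, per pairwise comparison, up to 10 genes per direction past the threshold, up to 3 members of each list with the smallest p, and, where fewer than 5 genes of a direction passed, those of that direction with the smallest unadjusted p, up to 5. A mean of at least 2 CPM in the higher group was required outside the lists. All genes of the last kind are named in the text. Which list members the text names was picked after their values had been seen. Genes without a symbol, sex-linked genes that could identify a donor, HLA genes, GSTM1, GSTT1, UGT2B17 and immunoglobulin or T cell receptor segments were left out. Fold changes of both exosome groups were compared across genes, beside 100 simulated sets of unchanged groups. In each set all 8 libraries, the PBS pair included, were redrawn with genes independent of each other.

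The procedure was tested on simulated data with the real means, library sizes and dispersions and 200 changed genes per set, in 5 sets. Among changed genes above 10 CPM, a 1.5-fold change was found in 82.4% of cases for activated against PBS, 81.7% for quiescent against PBS and 86.3% for activated against quiescent. A 1.25-fold change was found in 17.4%, 14.6% and 25.7%, and a 2-fold change in 98.7%, 98.0% and 98.0%. Over the 5 sets, 65, 72 and 54 unchanged genes were called. Changed genes found at any level were 25, 133, 179 and 223 for activated against PBS at 1.25-, 1.5-, 2- and 4-fold. They were 21, 138, 176 and 225 for quiescent against PBS and 37, 143, 183 and 228 for activated against quiescent. In each comparison, unchanged genes thus made up a larger share of all calls than the adjusted p threshold is meant to allow. In 20 simulated sets for activated against PBS, a list shifted 1.3-fold was called by camera in all 20, and other lists were called 8 times in total. Genes were drawn independently in all simulated sets. The estimated inter-gene correlation in the real data was 0.99 for the mitochondrial and 0.86 for the hypoxia list in that comparison. The simulated list calls therefore do not measure how often camera calls such lists falsely.

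Alternatives covered DESeq2 size factors in edgeR, no filter on low counts, a filter of at least 10 counts in at least 5 samples, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, fits of only the groups compared, the replicate number as a block (by title and by description), each library left out in turn and a threshold of 0.10. Added after the data had been seen were fits without the 3 libraries in which more than 60% of records were not uniquely aligned, and fits with that percentage as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.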

Results

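The data are gene counts from primary human airway epithelial cells, cultured as a polarised layer with an apical surface exposed to air. Each well of 1.9 square centimetres held about 100000 cells. The apical surface received 1 µL of PBS, alone or with 100000 exosomes, 24 h before harvest. Exosomes are small membrane vesicles that cells release. They came from neutrophils activated with 2 µM of the formylated peptide fMLP (the activated group, n = 3) or from quiescent neutrophils (the quiescent group, n = 3), and the PBS group had n = 2. Gene counts per library ranged from 18592010 in activated replicate 2 to 26366985 in quiescent replicate 2. The 8 libraries were close to each other: log-scale correlations across genes were 0.989 to 0.993 within groups and 0.987 to 0.993 between groups. No pair of libraries differed by as little as sampling noise. The closest pair, activated replicates 2 and 3, had a chi-square of 3.31 per degree of freedom, and the closest pair of libraries from different groups had 11.5. The other 6 pairs within a group had 15.8 to 67.0 (the PBS pair), so libraries of a group were not closer in general.

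**Figure D1:**
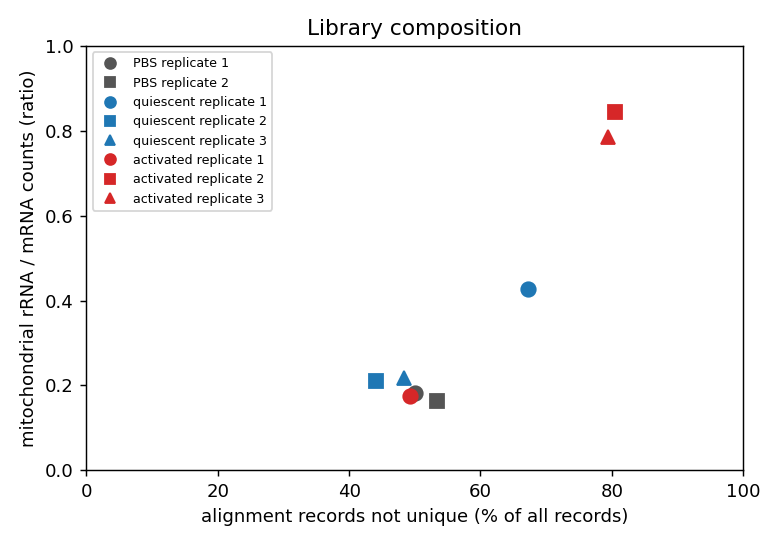
Share of alignment records that were not unique (horizontal axis, % of all records) and ratio of mitochondrial ribosomal RNA to mitochondrial messenger RNA counts (vertical axis) in each of the 8 libraries, coloured by group with a symbol per replicate. Activated replicates 2 and 3 and quiescent replicate 1 lie apart from the other 5 on both axes.

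Transcripts specific to neutrophils were almost absent in all 3 groups. MPO (myeloperoxidase), CTSG (cathepsin G), FCGR3B, CXCR1, FPR2, MNDA and MMP8 had 0 counts in every library, which allows at most 0.0477 CPM over the activated group, 0.0398 over the quiescent group and 0.0592 over the PBS group (3 counts of the group total, for counting error only). ELANE (neutrophil elastase) had 1 count over the activated libraries, 2 over the quiescent libraries and 2 over the PBS libraries, and CSF3R had 6, 5 and 7. PTPRC, which encodes the leukocyte surface protein CD45, had 0, 0 and 3. The neutrophil list differed between no pair of groups (camera adjusted p = 0.628, 0.507 and 0.853), and 7 of its 26 members were abundant enough to test, among them LCN2, which airway epithelium also makes.

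The first comparison asks what activated-neutrophil exosomes did to the epithelium relative to PBS. No gene passed the threshold in either direction. The higher genes with the smallest p were EMC7, LPAR6 and RBMXL1, at log2 differences of 0.28 ± 0.07, 0.28 ± 0.08 and 0.27 ± 0.08 (SE). EMC7, a subunit of the endoplasmic reticulum membrane complex, had 63.3 ± 0.616 CPM (SD, n = 3) in activated wells and 52.1 ± 2.17 (n = 2) in PBS wells. The lower genes with the smallest p were the long non-coding RNA MIAT (-1.32 ± 0.30), STRA6 (-0.35 ± 0.08), a retinol transporter, ADA2 (-0.77 ± 0.18), an adenosine deaminase, and CRTC2 (-0.41 ± 0.10), a coactivator of CREB. H4C4 (0.34), RN7SL128P (2.30 against 1.09 CPM) and KRT16P6 (-1.54) also met the rule for named genes, but H4C4 is 1 of several near-identical histone genes, the other pair are pseudogenes, and reads shared with other copies leave their values uncertain. Each of these 10 genes had an adjusted p of 0.96 in edgeR's quasi-likelihood test.

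Of the 32 gene lists, 5 passed in activated against PBS by camera with the preset correlation. None of them passed with an estimated one (adjusted p = 0.933 with an estimated correlation for oxidative phosphorylation, adjusted p = 0.76 with an estimated correlation for each of the others). Ciliated cell markers were lower (median log2 difference -0.22, 2 of 29 members above 0, adjusted p = 0.000121), among them the axonemal genes CCDC40 (-0.62 ± 0.23), DNAI1 (-0.48 ± 0.21) and DNAAF11 (-0.39 ± 0.16). Secretory and goblet cell markers were lower (median -0.16, adjusted p = 0.0433), with the mucins MUC1 at -0.36 ± 0.12 and MUC4 at -0.55 ± 0.19. Nuclear-encoded oxidative phosphorylation genes (median 0.06, adjusted p = 0.0432), such as NDUFA13 (0.33 ± 0.12) and NDUFA4 (0.24 ± 0.09), and replication-dependent histone genes (median 0.13, adjusted p = 0.0131), such as H4C8 (0.23 ± 0.09), were higher. Mitochondrially encoded transcripts were lower (median -1.81, adjusted p = 6.08e-08), with MT-ND4 at -2.92 ± 1.11 and MT-ND2 at -3.41 ± 1.28. Adjusted over the list alone, 2 members of 2 lists passed, G0S2 (-0.44 ± 0.13) of the neutrophil list and GADD45A (-0.35 ± 0.09) of the p53 list, and none passed over all genes tested.

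Of 17249 genes, 708 (4.1%) had an unadjusted p under 0.05 in edgeR for activated against PBS, where chance gives 862, and DESeq2 and limma-voom also called 0. Without PBS replicate 1 that count was 1776. This fit leaves PBS replicate 2 as the only control and takes it to vary like the other groups. In it 235 genes passed, 234 of them lower, and the ciliated list (adjusted p = 0.209, median -0.07), the oxidative phosphorylation list (0.0738, median 0.03) and the histone list (0.445, median -0.04) no longer passed. Camera's direction turned to lower for the last pair, while the median fell below 0 for the histone list only. The mitochondrial list turned in direction without PBS replicate 2 (median 0.17, adjusted p = 0.146). In activated replicates 2 and 3, 80.4% and 79.5% of alignment records were not unique, against 50.1% and 53.4% in the PBS libraries. The fit without these 2 libraries and quiescent replicate 1 has activated replicate 1 as its only activated library (n = 1) and takes its spread from the other groups, so it carries little weight. In it 0 genes passed, the secretory list did not pass (adjusted p = 0.913, median -0.02) and the oxidative phosphorylation list changed sign (0.705, median -0.02). Leaving out only PBS replicate 2, quiescent replicate 1, activated replicate 2 or activated replicate 3 also ended the call of the secretory list (0.633, 0.0674, 0.211 and 0.053), with medians of -0.11, -0.16, -0.05 and -0.13 where all libraries gave -0.16, and leaving out activated replicate 2 or 3 that of oxidative phosphorylation (0.366 and 0.187, medians 0.02 and 0.05). With the percentage of records not uniquely aligned as a covariate, the secretory (adjusted p = 0.115, median -0.10) and histone lists (0.0869, median 0.06) did not pass and oxidative phosphorylation turned in direction (0.279, median -0.03).

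Quiescent-neutrophil exosomes were compared with PBS in the same way, and again no gene passed. In edgeR with all libraries this comparison had the largest number of small p-values of the pairwise comparisons: 1558 genes (9.0%) had an unadjusted p under 0.05, 648 of them higher and 910 lower, where chance gives 862. The count was 2562 without PBS replicate 1 and 940 without PBS replicate 2, and in limma-voom it was 1023, below the 1255 of activated against quiescent. FBLN2, which encodes the matrix protein fibulin-2 (chromosome 3, 13549131 to 13638422), had 104.5 ± 7.89 CPM (SD, n = 3) in quiescent wells and 75.8 ± 4.65 (n = 2) in PBS wells, a log2 difference of 0.46 ± 0.08 (SE). ANXA1, which encodes annexin A1 (chromosome 9, 73151757 to 73170393), had 621.5 ± 20.9 and 485.4 ± 10.02 CPM (0.36 ± 0.07). The tight junction gene CLDN8 (0.44 ± 0.09), the transporter gene SLC16A9 (0.36 ± 0.07) and CYP4F3 (0.38 ± 0.08), a cytochrome P450 that hydroxylates leukotriene B4, were the other higher genes. The lower genes were FAM20A (-0.71 ± 0.13), GADD45A (-0.44 ± 0.09), CIITA (-0.57 ± 0.12), the master regulator of MHC class II genes, ZC3H12A (-0.35 ± 0.07), an RNase that degrades inflammatory transcripts, and the pseudogene KRT16P6 (-2.41 ± 0.37), whose reads may be shared with other keratin copies. KRT16P6 had an adjusted p of 0.366 and the other 9 had 0.527 in edgeR's quasi-likelihood test. All 10 genes separated the 3 quiescent from the 2 PBS libraries, as did 24.4% of all genes tested, where chance gives 20%.

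**Figure D2:**
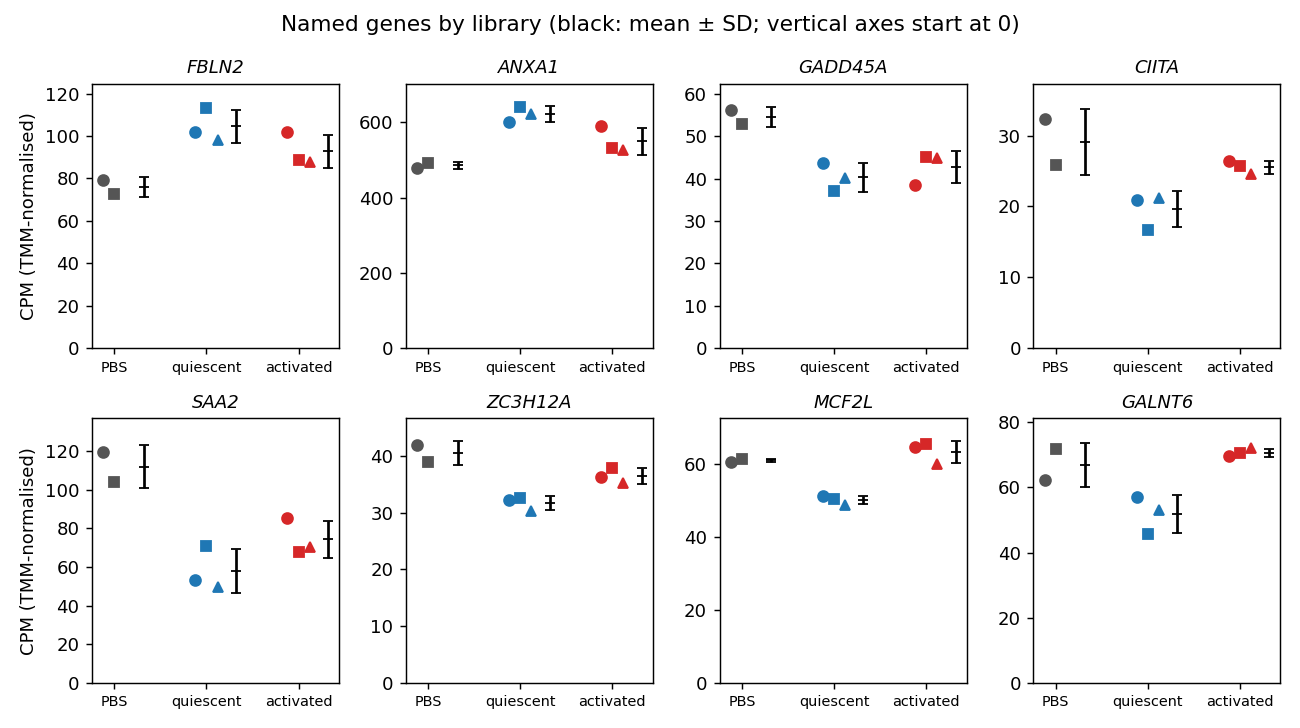
TMM-normalised CPM (vertical axes, from 0) of 8 named genes in each library, by group (circle, square and triangle for replicates 1, 2 and 3), with the group mean and SD in black beside the points (n = 2 for PBS, n = 3 for each exosome group). FBLN2 and ANXA1 lie higher and GADD45A, CIITA, SAA2 and ZC3H12A lower in the 3 quiescent libraries than in both PBS libraries, and MCF2L and GALNT6 lie lower in the quiescent than in the activated libraries; no gene passed adjusted p 0.05.

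By camera with the preset correlation, 10 lists passed in quiescent against PBS, and none of them with an estimated one. NF-kB target genes were lower (median -0.15, 7 of 24 members above 0, adjusted p = 0.000882, but adjusted p = 0.67 with an estimated correlation). They included SAA2 (-0.95 ± 0.17), an acute-phase serum amyloid A gene with a near-identical neighbour, at 58.0 ± 11.2 CPM (SD, n = 3) against 112.0 ± 11.05 (n = 2), and BCL3 (-0.45 ± 0.11), a regulator of NF-kB. The groups overlapped in the mean of the NF-kB list (log2, minus the mean over all 8 libraries). It was -0.19, -0.02 and -0.13 in quiescent replicates 1, 2 and 3, and 0.22 and -0.03 in PBS replicates 1 and 2. Adjusted over the list alone, 4 of its 24 members passed. Over all 32 lists 8 members passed in this way, and none over all genes. Hypoxia and glycolysis genes were higher as a list (median 0.27, adjusted p = 6.11e-10, but adjusted p = 0.688 with an estimated correlation), though only 5 of the 29 members had an unadjusted p under 0.05 and none passed, with GAPDH at 0.36 ± 0.12 and PGK1 at 0.27 ± 0.11, as were NRF2 and oxidative stress genes (median 0.11, 20 of 28 above 0, adjusted p = 0.000287, but adjusted p = 0.67 with an estimated correlation), with both subunits of glutamate-cysteine ligase, GCLC (0.27 ± 0.07) and GCLM (0.24 ± 0.07). Ribosomal protein genes (median 0.09, adjusted p = 0.000882; RPS20 0.27 ± 0.08), junction and polarity genes (0.06, 0.0202; the desmosomal gene DSG2 0.29 ± 0.09) and histone genes (0.07, 0.0396) were also higher. For these, the adjusted p was 0.688, 0.67 and 0.72 with an estimated correlation.

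Ciliated cell markers were lower (median -0.23, 4 of 29 above 0, adjusted p = 0.000287, but adjusted p = 0.688 with an estimated correlation), with CCDC40 at -0.66 ± 0.23 and DNAH9, an axonemal dynein, at -0.33 ± 0.12. The groups overlapped in the mean of this list (log2, minus the mean over all 8 libraries). It was -0.28, -0.21 and 0.25 in quiescent replicates 1, 2 and 3, and 0.24 and 0.11 in PBS replicates 1 and 2. Ionocyte markers (median -0.32, adjusted p = 0.0347), among them the chloride channel gene CFTR (-0.35 ± 0.14), cell cycle genes (median -0.18, 0.0446), such as BUB1 (-0.52 ± 0.19), and mitochondrially encoded transcripts (median -2.15, 6.89e-07), such as MT-ATP6 (-4.15 ± 1.35), were lower as well. For these, the adjusted p was 0.688, 0.766 and 0.688 with an estimated correlation. Other members with small p-values in lists that did not pass were MUC4 (-0.69 ± 0.19), SERPINA3 (-1.25 ± 0.32), the neutrophil chemokine gene CXCL2 (-0.64 ± 0.20), the interferon-stimulated gene IFITM1 (-0.47 ± 0.11), ITGA6 (0.25 ± 0.07) and the surfactant gene SFTPB (-2.37 ± 0.56), each with an adjusted p of 0.547 in edgeR. Much of the SFTPB difference rests on PBS replicate 1, with 1439 counts against 401 in PBS replicate 2. The quiescent libraries had 153, 185 and 189. By fry, which tests whether a list moves on balance 1 way, only the leukocyte list passed (adjusted p = 0.0209), with all 6 tested members above 0; its largest difference, LAPTM5 (1.58 ± 0.60), rests on 32 counts over 3 quiescent libraries and 7 over 2 PBS libraries.

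DESeq2 called 11 genes in quiescent against PBS, 4 higher and 7 lower, and limma-voom 0. Of the genes named for this comparison, 8 passed in DESeq2. Without PBS replicate 1, 278 genes passed in edgeR (22 higher, 256 lower), and the ciliated (adjusted p = 0.182, median -0.15), NF-kB (0.517, -0.08), NRF2 (0.112, 0.09), junction (0.074, 0.09) and ribosomal protein lists (0.909, 0.09) lost their call, as did the histone list (0.478, -0.09). The NRF2, junction and ribosomal protein medians were about as large as with all libraries or larger, although camera's direction turned to lower for the ribosomal protein list, as for the histone list. Without PBS replicate 2 the mitochondrial (0.886, median -0.09), cell cycle (0.944, -0.02) and ionocyte lists (0.42, 0.04) no longer passed, and 1 gene did, SFTPB. Camera's direction turned to higher for the cell cycle and ionocyte lists, and the median only for the latter. Without quiescent replicate 2 the cell cycle list (0.956, median -0.04) no longer passed and 1 gene did, SAA2. The junction list (0.111, median 0.04) was also lost without quiescent replicate 1, the ionocyte list (0.376, median -0.19) without quiescent replicate 3, and the histone list (0.111 and 0.218, medians 0.06 and 0.04) without either. The hypoxia list passed with any 1 library left out, with a median from 0.12 without quiescent replicate 2 to 0.41 without quiescent replicate 1. Its list means (log2, centred) were -0.02, 0.73 and 0.07 in quiescent replicates 1, 2 and 3. They were 0.04 and -0.32 in PBS replicates 1 and 2, and 0.15, -0.35 and -0.30 in activated replicates 1, 2 and 3. The groups thus overlapped. The estimated inter-gene correlation of this list was 0.86, far above the preset one, so repeated passing does not show that the quiescent libraries agreed. Without the 3 libraries with many records not uniquely aligned (n = 2 in each of these groups), 0 genes passed. The junction (0.0964, median 0.04) and histone lists (0.0964, median 0.06) did not pass either, the latter with a median about as large as the 0.07 of all libraries.

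**Figure D3:**
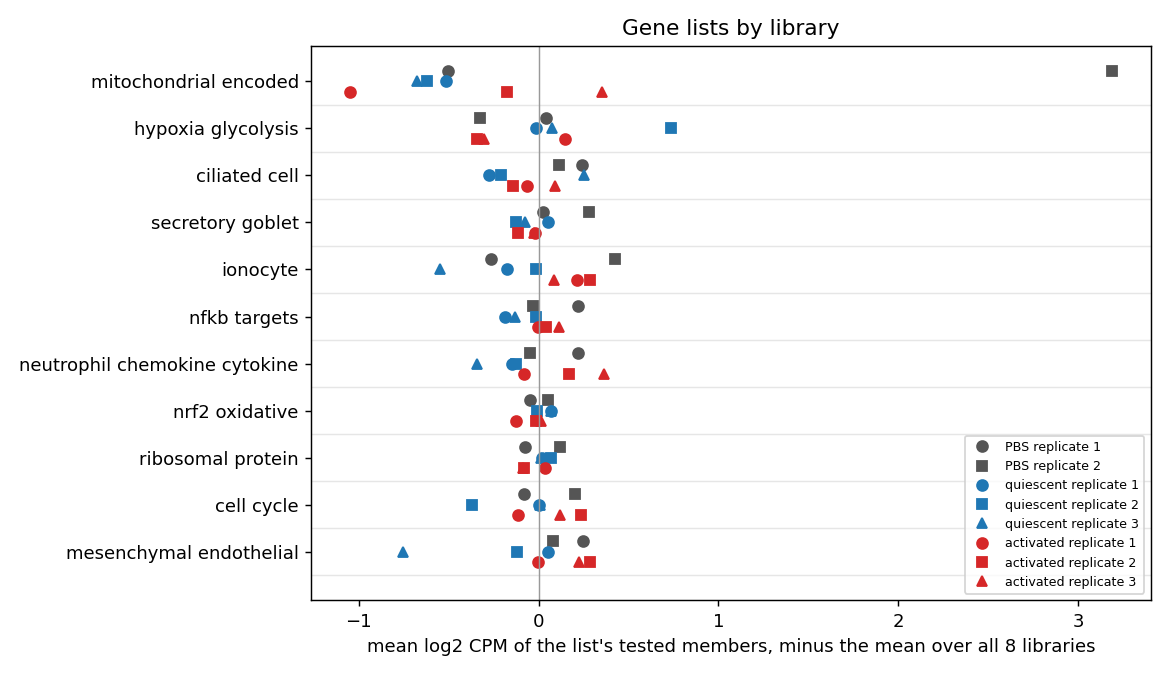
Mean log2 CPM of the tested members of 11 gene lists in each library, minus the mean over all 8 libraries (horizontal axis), coloured by group and with a symbol per replicate. PBS replicate 2 stands at 3.19 for mitochondrially encoded transcripts, where PBS replicate 1 is at -0.50 and the 6 exosome libraries lie between -1.05 and 0.35, and quiescent replicate 2 stands at 0.73 for hypoxia and glycolysis genes.

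The direct comparison of both exosome groups asks whether activation of the donor neutrophils mattered. No gene passed, and 709 genes (4.1%) had an unadjusted p under 0.05 in edgeR, where chance gives 862; DESeq2 and limma-voom called 0. With 1 library left out that count ran from 273 (without activated replicate 2) to 1232 (without activated replicate 1), was 331 without activated replicate 3 and 373 without quiescent replicate 2, and in limma-voom it was 1255. MCF2L, a guanine nucleotide exchange factor (chromosome 13, 112894378 to 113099739), had 63.3 ± 2.95 CPM (SD, n = 3) in activated and 50.1 ± 1.177 (n = 3) in quiescent wells, a log2 difference of 0.34 ± 0.06 (SE). GALNT6, which starts mucin-type O-glycosylation (0.44 ± 0.08), ACTBL2 (0.75 ± 0.17), PPM1K (0.27 ± 0.07) and the zinc transporter gene SLC39A8 (0.34 ± 0.09) were the other higher genes. ACTBL2 has close actin paralogs, and its reads may be shared. The lower genes were CPA4 (-0.50 ± 0.12), a carboxypeptidase, DHRS9 (-0.39 ± 0.10), a retinol dehydrogenase, the transcription factor SOX21 (-0.25 ± 0.06), ARHGAP22 (-0.61 ± 0.16) and the tubulin TUBB6 (-0.32 ± 0.08). The adjusted p was 0.969 for MCF2L and 0.999 for the other 9 in edgeR. Of all genes tested, 9.48% did not overlap between the groups, where chance gives 10%.

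By camera with the preset correlation 11 lists passed, and none of them with an estimated one: adjusted p = 0.598 with an estimated correlation for cell cycle, 0.817 for oxidative phosphorylation, 0.672 for immediate-early genes and 0.479 for each of the others. NF-kB targets were higher with activated than with quiescent exosomes (median 0.13, 19 of 24 members above 0, adjusted p = 3.59e-05), among them the feedback inhibitors TNFAIP3 (0.29 ± 0.10), NFKBIA (0.15 ± 0.06) and ZC3H12A (0.20 ± 0.07). Chemokine and cytokine genes were higher (median 0.32, 15 of 19 above 0, adjusted p = 0.00162), with the neutrophil-attracting CXCL2 at 0.61 ± 0.18 and CXCL5 at 1.00 ± 0.31. With 1 library left out, the median of this list ranged from 0.19 to 0.60. Its list means (log2, centred) were -0.08, 0.17 and 0.36 in activated replicates 1, 2 and 3. They were -0.15, -0.13 and -0.35 in quiescent replicates 1, 2 and 3, and 0.22 and -0.05 in PBS replicates 1 and 2. Against PBS, activated wells passed by camera with the preset correlation for neither list. The chemokine median was 0.06 there (adjusted p = 0.628) and the NF-kB median -0.03 (11 of 24 above 0, adjusted p = 0.614). Ionocyte markers were higher as a list (median 0.39, adjusted p = 8.19e-07), though only 3 of the 12 members had an unadjusted p under 0.05 and none passed, with CFTR at 0.30 ± 0.13, BSND at 0.71 ± 0.24 and ATP6V0D2, a proton pump subunit, at 1.41 ± 0.41. Cell cycle genes (median 0.19, adjusted p = 6.85e-05; BUB1 0.55 ± 0.18), oxidative phosphorylation genes (0.06, 0.00517) and immediate-early genes (0.15, 0.0193) were higher. Hypoxia and glycolysis genes were lower (median -0.28, 1 of 29 above 0, adjusted p = 9.67e-15), with GAPDH at -0.28 ± 0.11 and ALDOA at -0.36 ± 0.14. Ribosomal protein genes (median -0.08, 9.64e-08; RPL7 -0.14 ± 0.06), NRF2 genes (-0.07, 0.00488; GCLC -0.23 ± 0.06), basal cell markers (-0.07, 0.016; COL17A1 -0.27 ± 0.09) and squamous genes (-0.09, 0.0193; CNFN -0.61 ± 0.22) were lower. SFTPB had 24.1 ± 5.77 CPM (SD, n = 3) in activated and 6.99 ± 0.362 (n = 3) in quiescent wells.

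No list member passed when adjusted over its list alone. By fry the leukocyte list was lower (adjusted p = 0.0302; CD14 -0.24 ± 0.10). With any 1 library left out, 4 lists passed each time, the NF-kB, ionocyte, hypoxia and ribosomal protein lists, but with medians that moved. The hypoxia median ran from -0.43 without quiescent replicate 1 to -0.10 without quiescent replicate 2, whose list mean of 0.73 carries much of the difference. The ionocyte median ran from 0.22 without quiescent replicate 3 to 0.57 without quiescent replicate 2, the NF-kB median from 0.07 without activated replicate 3 to 0.16 without activated replicate 1, and the ribosomal protein median from -0.12 without activated replicate 1 to -0.06 without activated replicate 3. The chemokine list was lost without quiescent replicate 3 (adjusted p = 0.214, median 0.19) and the cell cycle and oxidative phosphorylation lists without quiescent replicate 2 (0.25 and 0.956, medians 0.04 and 0.01), and oxidative phosphorylation also without activated replicate 2 (0.15, median 0.04) or 3 (0.102, median 0.04). The basal, squamous and NRF2 lists were lost without quiescent replicate 1 (0.642, 0.401 and 0.345, medians -0.04, -0.01 and -0.05) or activated replicate 1 (0.0581, 0.448 and 0.232, medians -0.05, -0.04 and -0.02). The immediate-early list was lost without quiescent replicate 2 or 3 or activated replicate 2 or 3 (0.159, 0.145, 0.0601 and 0.516). Its medians were then 0.07, 0.14, 0.08 and 0.04, so without quiescent replicate 3 the call was lost with little change from 0.15. The fit without the 3 libraries with many records not uniquely aligned sets activated replicate 1 alone (n = 1) against 2 quiescent libraries, so it carries little weight. In it 0 genes passed, the basal (0.698, median -0.03), cell cycle (0.189, 0.10) and oxidative phosphorylation lists (0.816, 0.01) did not pass, and the ribosomal protein (0.816, 0.01) and immediate-early lists (0.852, -0.01) turned in direction. With the percentage of records not uniquely aligned as a covariate, the cell cycle (0.637, median 0.02) and ribosomal protein lists (0.0782, median -0.02) did not pass, and the oxidative phosphorylation (0.124, median -0.03) and immediate-early lists (0.637, median -0.04) turned in direction. The hypoxia list still passed (0.000462), with a median of -0.12 in place of -0.28.

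Against PBS, the mean of both exosome groups gave 0 genes past the threshold, with 1286 genes (7.46%) at an unadjusted p under 0.05 in edgeR, 450 higher and 836 lower, 3 by DESeq2 and 0 by limma-voom. The test for any difference among the 3 groups gave 0 in edgeR and in limma-voom, with 930 genes at an unadjusted p under 0.05. Without PBS replicate 1, these tests gave 319 and 200 genes, and 2348 and 1837 at an unadjusted p under 0.05. Without PBS replicate 2 the unadjusted count of the first was 787. For genes above 10 CPM the median SE of a log2 difference was 0.08 for activated against PBS, 0.08 for quiescent against PBS and 0.07 for activated against quiescent.

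Fold changes of both exosome groups against PBS were correlated across genes (Pearson r = 0.638, Spearman rho = 0.616, 17249 genes, which are not independent replicates), and 74.6% of genes had the same sign. Both use the same 2 PBS libraries, which alone gives a correlation. Simulated sets of unchanged groups, each with its own simulated PBS pair, gave a mean r of 0.589 (highest of 100 sets 0.616) and 70.2% with the same sign. Genes were drawn independently there, so shifts of a whole library were absent. Values above the simulated ones thus cannot tell a shared response from a shift in a PBS library. The covariance was 0.0476, against 0.0378 in the simulated sets (highest 0.041), a difference of 0.00971. Leaving out single libraries moved r between 0.45 without activated replicate 1 and 0.779 without PBS replicate 1, and unchanged groups were not simulated for these. Giving each exosome group 1 of the 2 PBS libraries as a separate control was not tried.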

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

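Of the tests in this part, those on library composition and on exosome exposure were chosen after the results had been seen, as were the fits with the percentage of records not uniquely aligned and without the 3 libraries; only the transcript length test was set before its result was seen. All groups held fewer than 4 libraries, so none was searched for single outlying values.

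The row of alignment records that were not unique, which only the added fits use, stood above both PBS libraries (50.1% and 53.4% of all records) in 3 of the 6 exosome libraries: 80.4% in activated replicate 2, 79.5% in activated replicate 3 and 67.2% in quiescent replicate 1. Exosome exposure as a cause that acts in all exosome wells is argued against by activated replicate 1 (49.2%), quiescent replicate 2 (44.1%) and quiescent replicate 3 (48.3%). These lay below both PBS libraries, so that 3 of 6 were higher. That count pools both kinds of exosome. It cannot decide on activated exosomes alone, for which replicates 2 and 3 were higher and replicate 1 was not. A candidate explanation is more ribosomal RNA in the 3 libraries: the ratio of mitochondrial ribosomal to mitochondrial messenger RNA counts was 0.845, 0.785 and 0.428 in them and 0.162 to 0.218 in the other 5, so the lowest of the 3 was 1.97 times the highest of the rest. Mitochondrial ribosomal RNA as a share of gene counts did not separate them. It was 0.734% in PBS replicate 2, whose mitochondrial messenger RNA share was 4.52%, and 0.435% in quiescent replicate 1. Nuclear ribosomal RNA itself was not measured by these gene counts, and a difference in library preparation stays open.

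Mitochondrially encoded transcripts were higher in PBS replicate 2, by 2.16-fold (MT-CO3) to 47.8-fold (MT-ND6) over PBS replicate 1, and made up 4.52% of its gene counts. That exosomes lowered them is argued against by PBS replicate 1, whose list mean of -0.50 (log2, centred) lay within the range of the 6 exosome libraries, -1.05 to 0.35. A preference for short transcripts in this library stays open, though a rank correlation cannot say whether it would reach a rise of 2.16-fold to 47.8-fold. Across 7942 nuclear protein-coding genes without a named pseudogene, the rank correlation of the library's ratio to PBS replicate 1 with transcript length was -0.245. Quiescent replicate 3, which lacks the rise, was more extreme at -0.386, which by the criterion first written counts against this cause, but the other 5 exosome libraries lay between -0.199 and 0.00136, and 1 library is too little to exclude it. This verdict, too, was changed after the values had been seen. For reads shared with pseudogenes, the median log2 difference between genes with and without a named pseudogene was 0.0138, within the range of the 6 exosome libraries (0.00789 to 0.0251), which by the criterion first written counts against this cause. The verdict was changed to undecided after that value had been seen, because a median does not see a rise in few genes: 4% of genes with a pseudogene were higher by over 0.5 on the log2 scale against 1.88% of genes without, and 0% to 0.813% of those with in the exosome libraries. The rise was 225 to 4798 CPM per kilobase of gene, with MT-ND6 on the other strand at 1613; no biological explanation within the PBS group was tested.

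Hypoxia and glycolysis genes had a list mean in the quiescent libraries that differed from the other 5 by 0.42 on the log2 scale (exact permutation p = 0.107, two-sided, 56 splits, smallest possible 0.0179), so exposure to quiescent-neutrophil exosomes stays open. The percentage of records not uniquely aligned stays open as a part of the cause: with it as a covariate over the 8 libraries, the difference went from 0.42 ± 0.22 to 0.29 ± 0.19 (SE), so that 69.8% was left. The mean percentage was 53.2% in quiescent, 51.7% in PBS and 69.7% in activated libraries, so the comparison of quiescent with PBS, where the list's median was 0.27 without and 0.29 with the covariate, cannot test it. In activated against quiescent the covariate moved the list's median from -0.28 to -0.12. Quiescent replicate 2 alone may account for most of it, since 44.2% of the difference was left without that library. What set this library apart was not recorded in the labels used here.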

How the results depend on the processing

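The fits without the 3 libraries with many records not uniquely aligned and with that percentage as a covariate were chosen after seeing the data. The count of 0 genes was the same in all 5 tests with DESeq2 size factors, a stricter filter, limma-voom with quality weights, fits of only the groups compared (where run), a threshold of 0.10 and both added fits. Without a filter on low counts, 58 genes passed for activated against PBS, 220 for quiescent against PBS, 70 for activated against quiescent, 148 for either exosome and 241 for any difference, with 36955 genes tested in place of 17249; the cause was not tested. The DESeq2 Wald test gave 11 genes for quiescent against PBS and 3 for either exosome, and the cause was not tested. Leaving out 1 library at a time gave 0 to 235 genes for activated against PBS, 0 to 278 for quiescent against PBS, 0 to 319 for either exosome, 0 to 200 for any difference and 0 in each case for activated against quiescent. The highest of these came without PBS replicate 1, where the only PBS library left was replicate 2. Of the nuclear protein-coding genes called there for activated against PBS, 33.2% have a named pseudogene, against 13.7% of those tested. These shares were not matched for expression level or transcript length, so they cannot tell whether shared reads caused the calls.

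Whether equal replicate numbers mark shared donors or days is not known. Same-numbered activated and quiescent libraries had correlations of their deviations from the group means of 0.04, -0.05 and 0.01. PBS and quiescent libraries had -0.17 by title number (1 with 1 and 2 with 2), and by description number 0.17 (PBS replicate 1 with quiescent replicate 2) and -0.03 (PBS replicate 2 with quiescent replicate 3). With the replicate block by title number, 2 genes passed for quiescent against PBS and 2 for either exosome, and 2 lists for activated against PBS; with the replicate block by description number, 0 genes passed in each test. The cause was not tested.

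For gene lists, an estimated correlation gave 0 in each of the 3 comparisons, and fry gave 0 for activated against PBS, 1 for quiescent against PBS and 1 for activated against quiescent. The preset correlation of 0.01 lies below the estimated one of most lists. Leaving out 1 library gave 4 to 11 lists for activated against PBS, 8 to 13 for quiescent against PBS and 9 to 13 for activated against quiescent. For activated against PBS, 8 lists passed without the 3 libraries, where 1 activated library is left, and 9 with the covariate; the cause was not tested. The correlation of both responses ranged from 0.45 to 0.779 with 1 library left out, for which no unchanged groups were simulated. It was 0.721 over genes of at least 10 CPM, where the simulated sets of unchanged groups, with genes drawn independently, gave a mean of 0.601 (highest 0.669).

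For 86 results on named genes, 1543 alternative values were computed: 1480 kept their direction and stayed short of the threshold, 61 kept it and passed (40 of them without a filter, 11 without PBS replicate 1 and 8 in DESeq2), and 2 reversed. These were MT-ND4 (0.31) and MT-ND2 (0.41) in activated against PBS without PBS replicate 2, the library with the high mitochondrial counts; with 1 library left out they ranged from -3.84 to 0.31 and from -4.36 to 0.41. Depth limits genes under 1 CPM most, where the median SE of a log2 difference was 0.46 in both comparisons with PBS.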

Other observations

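The genes in the first paragraph below were chosen for their abundance, after their values had been seen. The cultures carried a secretory profile at every treatment. BPIFA1 (43021 ± 7269 CPM, SD over 8 libraries), BPIFB1 (23374 ± 1890), SCGB3A1 (16666 ± 2946) and SLPI (14818 ± 736), which encode secreted proteins of airway surface liquid, were the most abundant transcripts, followed by PIGR (6961 ± 802), the transporter of polymeric immunoglobulins. SLPI inhibits neutrophil elastase, and its level spanned 14069 to 15904 CPM over the 8 libraries. Basal cell markers such as KRT5 (944.6 ± 80.1 CPM) and ciliated cell markers such as DNAH5 (96.6 ± 9.39) were both present, as were ionocyte markers such as CFTR (67.2 ± 10.8).

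Several lists that bear on injury by neutrophils passed in no comparison by camera. Interferon-stimulated genes had adjusted p of 0.888, 0.589 and 0.524 (activated against PBS, quiescent against PBS and activated against quiescent), protease inhibitors 0.483, 0.975 and 0.285, matrix metalloproteases 0.888, 0.975 and 0.853, matrix and collagen genes 0.628, 0.437 and 0.0641, TGF-beta and mesenchymal transition genes 0.628, 0.507 and 0.803, and unfolded protein response genes 0.628, 0.397 and 0.0656. Among matrix metalloproteases and related proteases, MMP14 had 348.2 ± 23.9 CPM over the 8 libraries. Mesenchymal and endothelial markers also passed in none (0.635, 0.0945 and 0.0757), and their list mean was lowest in quiescent replicate 3, at -0.76 (log2, centred) where the other 7 libraries lay between -0.12 and 0.28.

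The splits were set before their results were seen for activated against quiescent and for genes in quiescent against PBS, and the other counts below were chosen after the results had been seen. Of the 10 splits of the 6 exosome libraries into 3 and 3, which cannot give a share under 0.05, the real one gave 0 genes past the threshold and the highest other split gave 4. With a real count of 0, all 10 splits give at least as many whatever the data, so this count says nothing about chance. The split with 4 genes set quiescent replicate 1 and activated replicates 2 and 3, the libraries with many records not uniquely aligned, against the others, and had 1642 genes at an unadjusted p under 0.05 where the real split had 709 and the highest other split 1796. For gene lists by camera the real split gave 11 and the highest other 15, with 5 of 10 splits at 11 or more. In quiescent against PBS, the real split of 5 libraries gave 1558 genes at an unadjusted p under 0.05 and the highest other split 1881, with 2 of 10 splits as high, and 10 lists against a highest other of 16, with 8 of 10 splits at 10 or more. In activated against PBS, the real split gave 708 genes at an unadjusted p under 0.05 and the highest other 1111, with 4 of 10 splits as high, and 5 lists against a highest other of 12, with 9 of 10 splits at 5 or more. For the list counts and the counts of genes at an unadjusted p under 0.05, neither is chance excluded by so few splits nor can it be said that chance gave them.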
